A study of Homo sapiens with 8 samples.

How the data were processed

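Stranded mRNA libraries from MEG-01 cells were sequenced from both ends by the authors, in 4 groups of 2 libraries. Per the submitters' processing notes, reads were aligned with STAR 2.7 to hg38 and quantified with RSEM 1.3.1. The annotation release is not given in the sources used here. The deposited expected counts, made by the authors with RSEM at gene level and not normalized, cover 60754 genes in 8 libraries. The deposited TPM values, also from RSEM per the file headers, sum to between 999999.44 and 1000000.75 per library. The values were checked against these units, and expected counts were not whole in 7.05% to 7.83% of genes per library at a tolerance of 1e-06, which RSEM gives when reads fit more than 1 gene. Gene names were taken from a name table by Ensembl identifier. Chromosome positions were taken from GENCODE annotation of GRCh38 by the identifier without its version. The dose of Ceefourin 2 given alone is not given in the sources used here.

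Expected counts were rounded and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 17314, libraries were scaled by TMM (factors between 0.92 and 1.083), and quasi-likelihood tests were run on 1 fit of all 8 libraries with a mean per group. That fit left 4 residual degrees of freedom, to which edgeR added 3.95 by sharing spread across genes, and the common biological coefficient of variation was 13.6%. Contrasts were PMA against untreated, PMA plus Ceefourin 2 against PMA, Ceefourin 2 against untreated, and their interaction. Adjusted p values are Benjamini-Hochberg values over all tested genes in each contrast, and a gene was called below 0.05. Rose, fell and changed refer to called genes only. Standard errors are the absolute log2 fold change divided by the square root of F. Group levels are means of CPM with TMM scaling, and the spread is the SD of 2 libraries, so it is itself imprecise. A gene with 0 counts in a group is given as at least the ratio that 3 counts over the group would allow. A gene with 1 to 3 counts is given as a ratio with its 95% interval, and both cover counting error only.

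In addition, 39 lists holding 994 gene symbols were fixed before the files were seen, and 993 were matched to the deposited identifiers. The lists covered platelet and megakaryocyte biology, other blood and tissue cell types, ABC transporters, purine metabolism, the cell cycle, signalling, stress and metabolism. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 against all other genes, with Benjamini-Hochberg adjustment over the 39 lists. Camera with an estimated correlation and fry, a self-contained rotation test, were run beside it. With an estimated correlation, camera also tests on the 4 residual degrees of freedom, so a call lost there need not reflect correlation between members. The cyclic AMP list after PMA had an estimated correlation of 0.005, yet its camera adjusted p went from 0.000177 to 0.17. Some other lists called after PMA had higher estimates, with 0.135 for platelet, 0.253 for erythroid, 0.511 for DNA replication and 0.763 for mitosis genes. Where members correlate above the preset 0.01, the camera adjusted p at that preset can be too small. Counts of called members are given over all genes and adjusted over the list alone, and a single count means that both were equal.

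The genes named in the text followed a rule fixed before the files were seen. ABCC4 was named in every comparison. For each comparison the 10 largest rises and 10 largest falls were named among called protein-coding genes with at least 5 CPM in a compared group and no overlap between its libraries. One of the 10 largest rises after PMA carried no symbol and was not named, and 1 of the 10 largest falls after PMA and 1 further gene of the closing section are not reported here. From each list up to 4 called members with the smallest p were eligible, or the member with the smallest p where none was called, and members of the ABC transporter and megakaryocyte lists could be named with their values. Genes in other sets were named only where the text says so.

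The overlap of the Ceefourin 2 effects was tested with a one-sided Fisher's exact test over 17314 genes. The relation of the PMA effect to the Ceefourin 2 effect in PMA cells, which share the PMA libraries, was set against 20 simulations without any effect, and against 20 with the PMA effect kept and no Ceefourin 2 effect, which were added after the data were seen. Before use, the scripts were tested on simulated data for PMA plus Ceefourin 2 against PMA with 200 changed genes of 16708. They recovered 82% of 2-fold and 99% of 4-fold changes, 11.8% of 212 calls were unchanged genes, and 1 call arose in a comparison without changes. The endoplasmic reticulum chaperone list was moved by 0.5 log2 in the same simulation, in addition to the 200 genes. It was called by camera (adjusted p = 2e-17), with adjusted p = 0.032 with an estimated correlation and 0.0051 with fry. Genes were drawn independently, so this did not test camera where members correlate.

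Alternatives planned before the files were seen were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma voom, limma on log2(TPM + 1) and on log2(TPM + 0.1), no filter on low counts, a filter of 1 CPM in 2 libraries, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. In the last case the group left with 1 library was assumed to vary like the others. Leaving out PMA replicate 1 and PMA plus Ceefourin 2 replicate 1 together, and removing mitochondrially encoded genes, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9. With 2 libraries per group, no test on a single gene's ranks could reach significance, and all gene tests borrow spread across genes.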

Results

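Messenger RNA was sequenced from MEG-01 cells, an established human megakaryoblastic leukaemia line, in 4 groups of 2 libraries each. The groups were untreated cells, cells given PMA (a phorbol ester that activates protein kinase C and drives megakaryocytic differentiation) at 100 nM, cells given PMA with 20 µM Ceefourin 2 (an inhibitor of the transporter ABCC4), and cells given Ceefourin 2 alone, with treatments of 48 h. Expected counts summed to 44430292 and 57650835 in untreated replicates 1 and 2, 63165554 and 48595107 in PMA, 52982156 and 89950886 in PMA plus Ceefourin 2, and 59458967 and 58669250 in Ceefourin 2. Mitochondrially encoded transcripts took 2.55% and 3.94% of counts in the untreated replicates and 2.77% and 3.11% in Ceefourin 2. They took 9.61% and 4.53% in PMA replicates 1 and 2 and 8.32% and 4.94% in PMA plus Ceefourin 2, so the share moved with PMA and with its replicate 1. Component 1 of log2 CPM separated libraries with PMA from those without and held 79.6% of variance, and component 2 separated libraries with Ceefourin 2 from those without and held 6.4%.

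**Figure D1:**
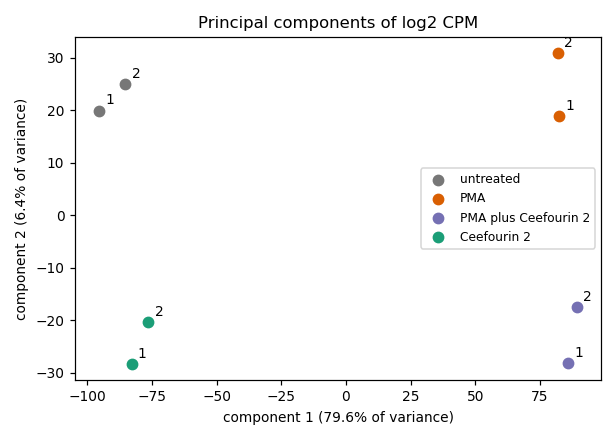
Principal components 1 and 2 of log2 CPM in the 8 libraries, coloured by group, with replicate numbers beside the points. Component 1 held 79.6% and component 2 held 6.4% of variance.

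The comparison of PMA with untreated cells asked how the transcriptome, and ABCC4 in it, changed during induced megakaryocytic differentiation. ABCC4, which encodes an exporter of cyclic nucleotides and thiopurine nucleotides and lies on chromosome 13 at 95019829 to 95301475 (GRCh38), rose from 325 ± 27 CPM (SD, n = 2) to 569 ± 35 CPM, a log2 fold change of 0.81 (SE 0.10, edgeR adjusted p = 0.00029). ITGB3, the beta chain of the platelet fibrinogen receptor, rose from 43.0 ± 3.4 to 909 ± 1.2 CPM (log2 fold change 4.40, SE 0.10), and its partner chain ITGA2B rose from 536 ± 55 to 1630 ± 120 CPM. The replication helicase subunit MCM3 fell from 582 ± 23 to 131 ± 7.0 CPM (log2 fold change -2.15, SE 0.09). In edgeR, 4838 of 17314 tested genes were called higher and 4443 lower after PMA at a Benjamini-Hochberg adjusted p below 0.05, and 2815 and 1781 of them changed at least 2-fold. On the deposited TPM values, which carry no TMM scaling, limma called 3197 genes higher and 5831 lower, so 35.4% of calls were higher against 52.1% in the edgeR fit. The median log2 fold change of all genes moved to -0.14 on that scale.

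The largest rises were in genes with almost no reads before treatment. DCSTAMP, a fusion receptor of osteoclasts and macrophages, had 0 counts in untreated cells and 23.8 ± 3.5 CPM after PMA, at least 869-fold higher. The growth factor chain PDGFB, which platelets store in alpha granules, rose at least 715-fold. Also at 0 in untreated cells were the adhesion gene LRRC4B (at least 446-fold), the potassium channel gene KCNK3 (at least 319-fold) and the keratin gene KRT79 (at least 184-fold). GZMB, a cytotoxic granule protease, rose by a ratio of 4620 (95% interval 1580 to 22400), and the sodium channel gene SCN7A by 1890 (522 to 15600). The chemokine CCL4, whose reads can be shared with its near copy CCL4L2, rose to 156 ± 30 CPM. A2M, a protease inhibitor carried in platelets, rose from 0.344 ± 0.071 to 323 ± 14 CPM. The largest falls were in ACPP (a phosphatase, log2 fold change -5.14), FAM43B (-5.03), the membrane gene GPM6B (-4.96), the BMP antagonist SOSTDC1 (-4.87), the cell cycle gene CDCA7 (-4.53), IGFL2 (-4.47), the sphingolipid transporter SPNS2 (-4.14), MS4A6A (-4.10) and the serine synthesis enzyme PHGDH (-3.99).

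Of 33 tested platelet and megakaryocyte surface and granule proteins, 30 rose and 1 fell, the same counts as adjusted over the list alone, and the median log2 fold change was 2.76. Among them PTGS1, the platelet cyclooxygenase, rose from 41.9 ± 2.3 to 653 ± 10 CPM, the tetraspanin CD9 rose from 0.0765 ± 0.039 to 18.9 ± 1.5 CPM, and the collagen receptor GP6 rose by 1.93. The ADP receptor gene P2RY1 was the member that fell (-0.67). The list was called higher by camera (adjusted p = 3.16e-12), and had adjusted p = 0.17 with an estimated correlation. Of 27 proplatelet cytoskeleton genes, 15 rose and 3 fell (4 fell when adjusted over the list alone), including rises in the adhesion protein VCL (2.43) and the actin crosslinker FLNA (1.66). That list was called higher (adjusted p = 0.00439), with adjusted p = 0.37 with an estimated correlation. Among 24 megakaryocyte and erythroid transcription factors, 10 rose and 7 fell (8 fell when adjusted over the list alone), and the list was not called (adjusted p = 0.781). GATA1 (0.95), GFI1B (2.02), TAL1 (1.09) and ETS1 (5.48) rose, while RUNX3 (-2.50) and the erythroid factor KLF1 (-1.56) fell. Its median of 0.04 became -0.11 on log2(TPM + 1). Granule biogenesis and secretion genes, of which 10 of 26 rose and 4 fell, had a median of 0.23, which became -0.02 on that scale, and were not called (adjusted p = 0.174).

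Erythroid genes moved the other way, with 20 of 31 lower and 9 higher. The alpha globin gene HBA2 fell from 141 ± 4.3 to 25.2 ± 4.8 CPM and the band 3 anion exchanger SLC4A1 fell by 3.70, while the fetal globin gene HBG2 rose from 2360 ± 410 to 12200 ± 1500 CPM. Reads of HBA2 and HBG2 can be shared with their near copies HBA1 and HBG1. Camera called the erythroid list lower (adjusted p = 0.0135), and it had adjusted p = 0.55 with an estimated correlation. The markers of other cell types were not called as lists. Of the monocyte and macrophage genes, 6 of 12 rose and 2 fell, with ITGAM lower by 3.90. Of the lymphoid genes 2 of 7 rose and 1 fell, of the endothelial genes 6 of 10 rose and 1 fell, and of the fibroblast and stromal genes 3 of 6 rose and 1 fell. Of the mast cell and basophil genes, 5 of 11 rose and 3 fell, with the IgE receptor chain FCER1A rising from 62.2 ± 0.15 to 251 ± 60 CPM. Of the stem and progenitor genes, 1 of 13 rose and 6 fell, with the homeobox gene HOXA9 lower by 2.16.

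All 37 DNA replication genes fell (median -1.22), and 35 of 37 mitosis and cytokinesis genes fell, among them the spindle motor KIF11 (-1.52). Camera called both lower, at adjusted p = 2.03e-12 and 1.31e-08, with adjusted p = 0.37 and 0.45 with an estimated correlation. The cell cycle inhibitor CDKN1A rose from 5.45 ± 0.45 to 184 ± 19 CPM, in a list of 23 inhibitors and G1 cyclins of which 9 rose and 7 fell. Ribosome biogenesis and MYC target genes fell in 27 of 33 cases and rose in 1, with the nucleolar methyltransferase FBL lower by 1.25, and were called lower (adjusted p = 3.75e-07, adjusted p = 0.44 with an estimated correlation). Of 28 purine and thiopurine metabolism genes, 18 fell and 4 rose. PAICS, an enzyme of purine synthesis, fell from 506 ± 11 to 184 ± 0.92 CPM, and SLC29A1, a nucleoside importer, fell from 199 ± 15 to 68.1 ± 5.5 CPM. Camera called that list lower (adjusted p = 0.00106, adjusted p = 0.37 with an estimated correlation). Of 20 ABC transporters, 12 rose and 4 fell, without a list call (adjusted p = 0.0549). The drug exporter ABCB1 rose from 19.0 ± 0.40 to 200 ± 15 CPM and ABCA7 rose by 2.52, while the mitochondrial transporter ABCB10 (-1.42) and the exporter ABCG2 (-1.92) fell.

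Signalling and immune lists were called higher. Of 32 immediate early and MAPK feedback genes, 28 rose and 2 fell (3 fell when adjusted over the list alone), with the collagenase MMP1 up by 5.98. Of 26 NF-kB targets and cytokines, 21 rose and 2 fell, with CCL2 up from 1.77 ± 0.22 to 134 ± 12 CPM and IRF1 up by 2.74. Of 36 interferon-stimulated genes, 29 rose and 3 fell, with RSAD2 higher (2.14), and 15 of 19 MHC and antigen presentation genes rose. Their camera adjusted p were 4.72e-08, 9.36e-07, 1.8e-06 and 0.000124, with adjusted p = 0.37, 0.37, 0.45 and 0.17 with an estimated correlation. Of 32 cyclic AMP signalling genes, 20 rose and 4 fell, with the cyclic GMP phosphodiesterase PDE5A up by 5.48 (list adjusted p = 0.000177, adjusted p = 0.17 with an estimated correlation). The hyaluronan receptor CD44 rose from 269 ± 6.2 to 2470 ± 150 CPM, within 29 integrin and matrix adhesion genes of which 26 rose and 2 fell (adjusted p = 7.02e-09, adjusted p = 0.084 with an estimated correlation). Lysosome and autophagy genes rose in 24 of 29 cases (26 when adjusted over the list alone), with the autophagy receptor SQSTM1 up by 2.53 (adjusted p = 4.74e-07, adjusted p = 0.17 with an estimated correlation).

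Of 31 ATF4 and amino acid response genes, 15 fell and 2 rose (adjusted p = 0.00898, adjusted p = 0.76 with an estimated correlation), and the call was lost without untreated replicate 2 (adjusted p = 0.063). Of 26 cholesterol genes, 15 fell and 4 rose (adjusted p = 0.042, adjusted p = 0.55 with an estimated correlation). Without untreated replicate 1, PMA replicate 2, Ceefourin 2 replicate 1 or Ceefourin 2 replicate 2 the cholesterol call was lost (adjusted p = 0.079, 0.099, 0.054 and 0.052), as it was with a filter of 1 CPM in 2 libraries (0.062) and with the replicate number as a block (0.056). Of 13 mitochondrially encoded transcripts, 9 rose (10 when adjusted over the list alone), with a median of 1.24 (adjusted p = 0.0384, adjusted p = 0.71 with an estimated correlation). MT-CO1, a subunit of the respiratory chain, rose from 7200 ± 2100 to 21000 ± 12000 CPM, a log2 fold change of 1.55 (SE 0.42). Over the fits without 1 library its log2 fold change ranged from 0.82 to 2.04, and its call did not hold in all of them. Without PMA replicate 1 or untreated replicate 1 the mitochondrial list had adjusted p = 0.17 and 0.14, and without Ceefourin 2 replicate 1 or replicate 2 it had 0.054 and 0.052, and with the replicate block 0.057. With PMA replicate 1 and PMA plus Ceefourin 2 replicate 1 both left out, 1 of the 13 transcripts rose and the median was 0.60.

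Among lists without a call after PMA, 7 of 17 protein kinase C genes rose and 4 fell, 3 of 16 fatty acid synthesis genes rose and 7 fell (8 fell when adjusted over the list alone), and 6 of 21 endoplasmic reticulum chaperones rose and 5 fell (5 and 5 when adjusted over the list alone). Of the NRF2 targets 10 of 23 rose and 6 fell (11 and 7 when adjusted over the list alone), and of the aryl hydrocarbon receptor targets 4 of 6 rose. Heat shock genes rose in 2 and fell in 6 of 20 cases, metallothionein and zinc genes rose in 3 and fell in 3 of 9, and p53 targets rose in 10 and fell in 4 of 22 (5 fell when adjusted over the list alone). BCL2 family genes rose in 12 and fell in 5 of 24 cases, hypoxia and glycolysis genes rose in 9 and fell in 10 of 33, and oxidative phosphorylation genes rose in 4 and fell in 11 of 40 (8 fell when adjusted over the list alone). Replication-dependent histones, which mRNA selection captures poorly, rose in 7 and fell in 1 of 15. The medians of the cell cycle inhibitors, chaperones, NRF2 targets and metallothioneins, at 0.07, 0.11, 0.21 and 0.12, turned negative on log2(TPM + 1), at -0.08, -0.17, -0.03 and -0.06. Camera called 17 of 39 lists in this comparison, 10 higher and 7 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.084. The rotation test fry, which does not compare a list with other genes, called 29.

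**Figure D2:**
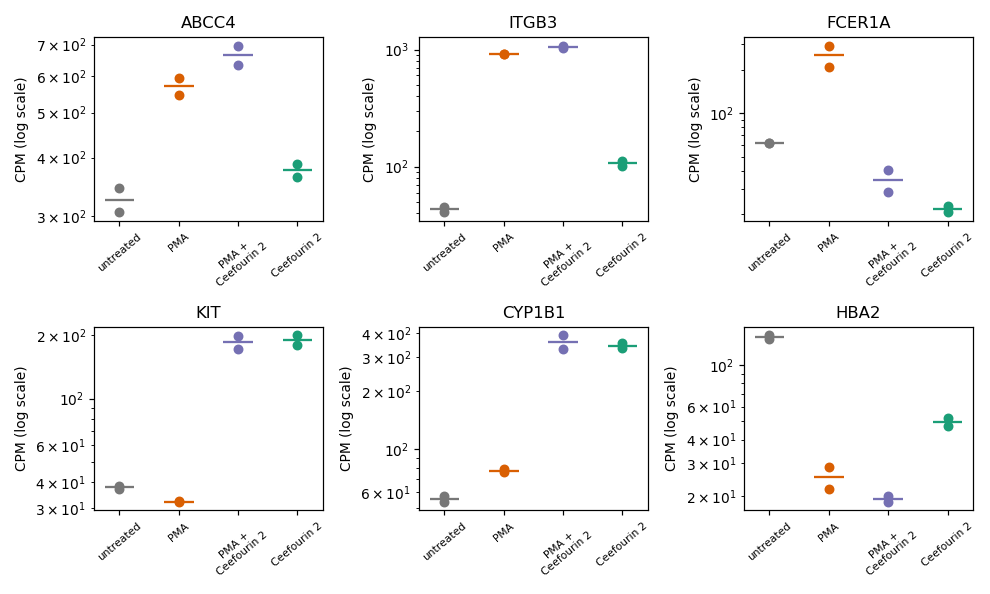
Expression of 6 genes in CPM (log scale) in the 8 libraries; points are libraries and lines are group means of 2 libraries. ABCC4 had means of 325, 569, 664 and 375 CPM in untreated, PMA, PMA plus Ceefourin 2 and Ceefourin 2 cells.

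The comparison of PMA plus Ceefourin 2 with PMA alone asked what the ABCC4 inhibitor changed in differentiating cells. ABCC4 itself was at 664 ± 45 CPM with the inhibitor and 569 ± 35 CPM without (log2 fold change 0.22, SE 0.10, edgeR adjusted p = 0.37) and was not called, but with the replicate number as a block it was called higher (0.22, adjusted p = 0.031). KIT, the stem cell factor receptor on chromosome 4 at 54657918 to 54740715, rose from 32.3 ± 0.19 to 185 ± 19 CPM (log2 fold change 2.52, SE 0.10, adjusted p = 0.00017). CYP1B1, an oxidase induced through the aryl hydrocarbon receptor, rose from 77.6 ± 2.2 to 360 ± 42 CPM (2.21, SE 0.10, adjusted p = 0.00022). FCER1A fell from 251 ± 60 to 34.4 ± 8.7 CPM (-2.86, SE 0.21, adjusted p = 0.002). SELP, the adhesion receptor of alpha granules, fell from 21.9 ± 9.4 to 2.57 ± 0.76 CPM (-3.07, SE 0.33, adjusted p = 0.0063). In edgeR, 159 genes were called higher and 158 lower of 17314, and 87 and 92 of them changed at least 2-fold. The total of 317 calls fell to 109 without PMA replicate 1, 40 without PMA replicate 2, 21 without PMA plus Ceefourin 2 replicate 1 and 72 without its replicate 2. With PMA replicate 1 and PMA plus Ceefourin 2 replicate 1 both left out, 1 call remained, at 1 library per group. All 48 called genes named for this comparison kept their direction in every such fit. For the largest rises and falls that was set beforehand, since they were named only where libraries did not overlap. The other genes had passed the test on the same libraries, so their kept direction is weak support too. IL24, KIT, RGS9, CYP1B1, TNFAIP8L3, CSPG4, FCER1A, CCL23, GPR85, ABCG2, PLEK, KDR and PRKAR2B, 13 of the 48, stayed called without any 1 library. On log2(TPM + 0.1) limma called 69 higher and 111 lower, so 38.3% of calls were higher against 50.2%. Other alternatives raised the number, with 443 higher and 330 lower in the DESeq2 Wald test and 821 and 661 with the replicate number as a block.

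Other large rises with the inhibitor in PMA cells were in the WNT antagonist NKD2 (2.99), the cytokine IL24 (2.97), the interferon-induced GTPase GBP5 (2.46), the G protein regulator RGS9 (2.30), TNFAIP8L3 (2.04), the metalloprotease ADAMTS7 (1.96), the neuronal adhesion gene MDGA1 (1.93) and the calcium-binding gene CABP7 (1.90). Large falls were in the proteoglycan CSPG4 (-3.13), the chemokine CCL23 (-2.64), the scaffold gene DLGAP3 (-2.35), the chemokine-binding Duffy antigen ACKR1 (-2.22), the orphan receptor GPR85 (-2.22), TEX9 (-2.18), the blood group gene SMIM1 (-2.16) and the adaptor FYB1 (-2.16). Of 33 platelet and megakaryocyte proteins, 3 rose and 4 fell (5 and 10 when adjusted over the list alone), with a median of -0.24. PLEK, a protein kinase C substrate of platelets, fell from 600 ± 97 to 202 ± 4.7 CPM, the podoplanin receptor CLEC1B fell by 2.63 and the G protein regulator RGS18 fell by 1.33. CD9 (1.66) and PTGS1 (0.49) rose, and the fibrinogen receptor chains ITGA2B (0.08, adjusted p = 0.9) and ITGB3 (0.22, adjusted p = 0.33) were not called. Camera called the list lower (adjusted p = 0.0444, adjusted p = 0.69 with an estimated correlation). The call was lost without untreated replicate 1 or 2 (adjusted p = 0.052 and 0.053), PMA replicate 2 (0.22), PMA plus Ceefourin 2 replicate 1 (0.084), or Ceefourin 2 replicate 1 or 2 (0.086 and 0.084). Transcription factors showed 3 rises and 1 fall among 24 (5 and 5 when adjusted over the list alone), with ETS1 (1.47) and CEBPA (1.48) higher and SPI1 lower (-1.26).

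Of 6 aryl hydrocarbon receptor targets, 3 rose (6 when adjusted over the list alone), with a median of 1.21. CYP1A1 rose from 0.724 ± 0.35 to 4.87 ± 0.42 CPM and the receptor's feedback gene TIPARP from 32.3 ± 0.45 to 74.1 ± 11 CPM. The list was called higher (adjusted p = 1.11e-06, adjusted p = 0.18 with an estimated correlation). Immediate early genes rose in 2 of 32 cases, LIF (1.21) and MMP1 (1.22), and in 11 when adjusted over the list alone (adjusted p = 4.39e-05, adjusted p = 0.64 with an estimated correlation). Called higher with 1 gene each were the endothelial list (4 genes when adjusted over the list alone), with the VEGF receptor KDR up from 31.4 ± 1.7 to 108 ± 3.8 CPM, and the fibroblast list, with PDGFRA up by 1.02. Their adjusted p were 0.0123 and 0.0118, with adjusted p = 0.59 and 0.47 with an estimated correlation. Without PMA plus Ceefourin 2 replicate 1 the endothelial list had adjusted p = 0.074. The BCL2 family list, with 1 of 24 higher, MCL1 by 0.51 (3 rises and 1 fall when adjusted over the list alone), and the hypoxia and glycolysis list, with 2 of 33 higher, among them the glucose transporter SLC2A1 by 0.73 (4 rises when adjusted over the list alone), were also called higher. Their adjusted p were 0.00667 and 0.0118, with adjusted p = 0.43 and 0.69 with an estimated correlation. With PMA replicate 1 and PMA plus Ceefourin 2 replicate 1 both left out, the endothelial and BCL2 family calls were lost (adjusted p = 0.087 and 0.082). Mast cell and basophil genes were called lower, with 3 of 11 falling and 1 rising (1 rise and 6 falls when adjusted over the list alone). The histamine-forming enzyme HDC fell from 507 ± 38 to 269 ± 14 CPM. Erythroid genes were called lower with 3 of 31 falling (9 falls and 1 rise when adjusted over the list alone), among them HBD (-1.49) and the carbonic anhydrase CA1 (-1.66). Both lists had adjusted p = 0.000787, and adjusted p = 0.47 and 0.69 with an estimated correlation.

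DNA replication genes had 0 of 37 called, 0 when adjusted over the list alone, a median of -0.10 and the smallest p in PRIM1 (-0.49, adjusted p = 0.13, and 0.036 with the replicate block). The list was called lower (adjusted p = 0.00437, adjusted p = 0.70 with an estimated correlation), and the call was lost without PMA replicate 2 (0.66) or PMA plus Ceefourin 2 replicate 1 (0.33). NRF2 targets fell in 2 of 23 cases, with the heme transporter SLC48A1 lower by 0.65 (adjusted p = 0.0239, adjusted p = 0.69 with an estimated correlation), and the call was lost without the same 2 libraries (0.067 and 0.2), and with PMA replicate 1 and PMA plus Ceefourin 2 replicate 1 both left out (0.18). Cyclic AMP signalling genes fell in 3 of 32 cases (2 rises and 4 falls when adjusted over the list alone) without a list call (adjusted p = 0.494). The kinase subunit PRKAR2B fell from 293 ± 14 to 120 ± 16 CPM, PDE5A fell by 1.32 and the coactivator partner CITED2 by 1.24. Of the ABC transporters, ABCG2 rose from 1.63 ± 0.050 to 5.86 ± 0.93 CPM and ABCB1 was at 147 ± 16 against 200 ± 15 CPM (adjusted p = 0.078, and 0.0063 with the replicate block). NF-kB targets had IL1A higher (1.60) and CCL4 lower (-1.77), the interferon-stimulated gene RSAD2 rose by 1.15 and the lysosomal protease CTSL rose by 0.78, and none of these 3 lists was called. Camera called 11 of 39 lists, 6 higher and 5 lower, fry called 6, and 0 held with an estimated correlation (lowest adjusted p = 0.18).

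Genes that PMA had raised and the inhibitor lowered numbered 96, where 44.1 were expected if the calls were independent, and genes that PMA had lowered and the inhibitor raised numbered 23, where 40.8 were expected. Genes moved the same way by both numbered 115 higher, where 44.4 were expected, and 30 lower, where 40.5 were expected. Genes raised by PMA were thus more than expected among inhibitor calls in both directions, so the 96 alone do not show a reversal. Both comparisons used the same PMA libraries, which alone pushes their log2 fold changes apart. Over 17314 genes their correlation was -0.0311 and their covariance -0.0183. Simulated counts with the PMA effect kept and no inhibitor effect gave -0.125 and -0.0535, and simulated counts with no effect in any group gave -0.515 and -0.0555, so the correlation depends on the size of the PMA effect. The 20 simulations with the PMA effect kept ran from -0.138 to -0.11 in correlation and from -0.0587 to -0.0469 in covariance. The observed values were less negative than all of these, so they show no excess of opposition over all genes. The simulated libraries varied independently, without deviations shared by replicate number. The 119 opposed genes fell to 50 without PMA replicate 1, 20 without PMA replicate 2, 11 without PMA plus Ceefourin 2 replicate 1 and 31 without its replicate 2.

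The comparison of Ceefourin 2 with untreated cells asked what the inhibitor did without PMA. ABCC4 was at 375 ± 17 CPM against 325 ± 27 CPM (log2 fold change 0.21, SE 0.10, edgeR adjusted p = 0.41) and was not called, but with the replicate number as a block it was called higher (0.21, adjusted p = 0.038). CYP1B1 rose from 55.6 ± 2.9 to 343 ± 14 CPM (2.63, SE 0.11, adjusted p = 0.00013) and KIT from 37.7 ± 1.0 to 190 ± 15 CPM (2.33, SE 0.10, adjusted p = 0.00015). ITGB3 rose from 43.0 ± 3.4 to 107 ± 7.0 CPM (1.31, SE 0.09, adjusted p = 0.0015). HBA2 fell from 141 ± 4.3 to 49.5 ± 3.4 CPM (-1.51, SE 0.13, adjusted p = 0.0037). In edgeR, 166 genes were called higher and 125 lower, and 73 and 72 of them changed at least 2-fold. The total of 291 calls was 30 without untreated replicate 1, 36 without untreated replicate 2, 115 without Ceefourin 2 replicate 1 and 127 without its replicate 2. Leaving out a library outside the comparison, which lowers the number of libraries behind the dispersion, gave 186 without PMA replicate 1, 188 without PMA replicate 2, and 166 and 169 without PMA plus Ceefourin 2 replicates 1 and 2. With only the 4 libraries compared in the fit there were 31. Other alternatives raised the number, with 488 higher and 312 lower in the DESeq2 Wald test and 807 and 623 with the replicate number as a block. All 47 called genes named for this comparison kept their direction in every such fit. The naming rule again set this beforehand for the largest rises and falls. CYP1B1, KIT, TMEM200A, CDKN1A, DHRS3, SELPLG, S100A4, SULT1A4, IGFBP5, ITGB3, HBA2, KDR, ITGB7 and AHRR, 14 of the 47, stayed called without any 1 library. Calls were 75.7% higher without Ceefourin 2 replicate 1, against 57% with all libraries.

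Other large rises with Ceefourin 2 alone were in the immediate early gene IER3 (2.26), the semaphorin receptor NRP1 (2.22), GBP5 (2.22), the membrane gene TMEM200A (2.06), CDKN1A (1.81), the protease inhibitor SERPINB2 (1.81) and the myeloid factor CEBPA (1.81). AHRR, the repressor of the aryl hydrocarbon receptor, rose by 2.35, but the deposited table holds it under 2 gene identifiers that can divide its reads, so its level is uncertain. Large falls were in the retinal reductase DHRS3 (-2.35), the complement factor CFP (-2.20), the erythroid pyruvate kinase PKLR (-2.13), the beta globin gene HBB (-2.08), the selectin ligand SELPLG (-2.07), the calcium-binding protein S100A4 (-1.96), the adaptor SLA2 (-1.95) and IGFBP5 (-1.85). The nearly identical sulfotransferase genes SULT1A3 (-2.05) and SULT1A4 (-1.84) share reads. Of 31 erythroid genes, 14 fell and 0 rose (24 and 0 when adjusted over the list alone), and the median was -1.14. HBD fell from 18.6 ± 1.5 to 6.94 ± 0.34 CPM, and the transcription factor list held KLF1 lower (-0.98). The erythroid list was called lower (adjusted p = 1.49e-21, adjusted p = 0.17 with an estimated correlation).

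The cholesterol, fatty acid and endoplasmic reticulum chaperone lists were called higher with Ceefourin 2 alone. Of 26 cholesterol genes, 5 rose (22 when adjusted over the list alone), with a median of 0.57. INSIG1, a sterol sensor, rose from 93.0 ± 9.2 to 174 ± 27 CPM, and the enzymes MVD (1.02) and DHCR7 (0.63) rose. Fatty acid synthesis genes rose in 2 of 16 cases (6 rises and 1 fall when adjusted over the list alone), with the desaturase FADS2 up from 498 ± 28 to 789 ± 85 CPM. Of 21 endoplasmic reticulum chaperones, 7 rose (17 when adjusted over the list alone), among them CRELD2 (0.94), DNAJB11 (0.60) and the disulfide isomerase PDIA4 (0.72). Their camera adjusted p were 4.12e-13, 6.79e-06 and 3.72e-13, each with adjusted p = 0.17 with an estimated correlation. Aryl hydrocarbon receptor targets rose in 4 of 6 cases (6 when adjusted over the list alone), with CYP1A1 (2.88), TIPARP (0.74) and the receptor gene AHR (1.10) higher (adjusted p = 1.49e-08, adjusted p = 0.14 with an estimated correlation). Immediate early genes rose in 6 of 32 cases (17 when adjusted over the list alone), with the phosphatase DUSP5 (1.34) and MMP1 (1.66) higher (adjusted p = 5.89e-13, adjusted p = 0.17 with an estimated correlation). BCL2 family genes had 0 of 24 called over all genes and 4 rises and 1 fall when adjusted over the list alone (adjusted p = 0.00943, adjusted p = 0.17 with an estimated correlation).

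The remaining list calls without PMA were each lost in at least 1 fit without 1 library. With the replicate number as a block all of them held, at camera adjusted p between 0.00024 and 0.033. Without 1 library the replicate numbers are not balanced between groups, so these losses need not come from that library alone. Cyclic AMP genes rose in 2 of 32 cases (8 rises and 2 falls when adjusted over the list alone), with the clock gene PER1 up by 0.77 (adjusted p = 0.0102, adjusted p = 0.17 with an estimated correlation), and the call was lost without untreated replicate 2 (0.13) or Ceefourin 2 replicate 1 (0.069). Mast cell genes fell in 3 and rose in 1 of 11 cases (4 falls and 1 rise when adjusted over the list alone), with FCER1A lower by 1.53 (adjusted p = 0.0387, adjusted p = 0.47 with an estimated correlation), and the call was lost without the same libraries (0.11 and 0.069). NF-kB targets rose in 1 of 26 cases, or 5 when adjusted over the list alone (adjusted p = 0.0387, adjusted p = 0.81 with an estimated correlation), and the call was lost without untreated replicate 1 (0.32) or Ceefourin 2 replicate 2 (0.18), and with DESeq2 size factors (0.056). NRF2 targets fell in 1 of 23 cases (adjusted p = 0.00943, adjusted p = 0.65 with an estimated correlation), and the call was lost without untreated replicate 2 (0.098). Oxidative phosphorylation genes had 0 of 40 called and a median of -0.10 (adjusted p = 0.00529, adjusted p = 0.85 with an estimated correlation), with the call lost without untreated replicate 2 (0.36) or Ceefourin 2 replicate 1 (0.14). Integrins rose in 2 and fell in 1 of 29 cases (4 and 2 when adjusted over the list alone), with ITGB7 lower by 2.25 (adjusted p = 0.0206, adjusted p = 0.17 with an estimated correlation). Their median of 0.22 and mean of -0.06 differed in sign, and without either untreated or either Ceefourin 2 replicate the adjusted p lay between 0.053 and 0.069. ATF4 targets had 0 of 31 called and were called higher as a list (adjusted p = 0.0118, adjusted p = 0.85 with an estimated correlation). Without untreated replicate 1 that call was lost (0.5), and without Ceefourin 2 replicate 2 the list was called lower (0.015). Outside called lists, CD36 (-1.66) fell and GP6 (0.96) and the thrombin receptor F2R (0.77) rose among 33 platelet proteins, of which 5 rose and 1 fell (7 and 5 when adjusted over the list alone). ITGAM (-1.59), the progenitor marker CD34 (-1.63), MCM3 (-0.54) and the protease CTSS (-0.91) fell, KDR (1.04) rose, and 0 of 20 ABC transporters were called. Camera called 14 of 39 lists, 10 higher and 4 lower, and 9 without untreated replicate 2. With fry 12 were called, and 0 held with an estimated correlation (lowest adjusted p = 0.14).

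**Figure D3:**
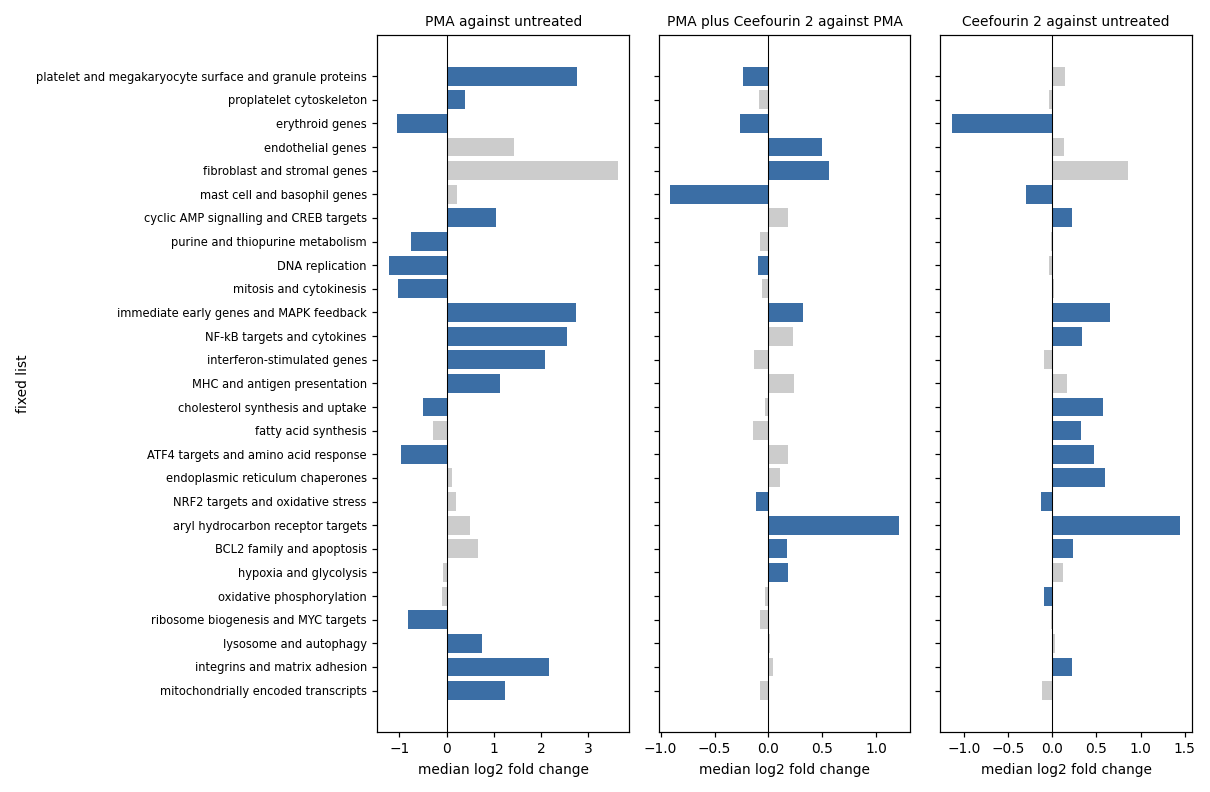
Median log2 fold change of each fixed list that camera called in at least 1 of 3 comparisons, with 1 panel per comparison and a separate scale in each. Blue bars were called at an adjusted p below 0.05 and grey bars were not, and aryl hydrocarbon receptor targets had medians of 0.50, 1.21 and 1.45.

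The effects of Ceefourin 2 with and without PMA come from separate libraries, but from 1 fit that shares the dispersion of each gene. They were compared directly, and the exact test below treats genes as independent and does not measure variation between libraries. CYP1B1, KIT, GBP5, KDR, CYP1A1 and TIPARP rose in both states, and FCER1A and HBD fell in both. Genes raised in both numbered 45, where 1.5 were expected by chance (one-sided Fisher's exact p = 9.72e-55), and genes lowered in both numbered 30, where 1.1 were expected (p = 1.2e-34, same exact test). Another 3 genes were called in opposite directions, a count for which no expected number was computed. The 45 fell to 8 and 12 without untreated replicates 1 and 2, 21 and 14 without PMA replicates 1 and 2, 9 and 20 without PMA plus Ceefourin 2 replicates 1 and 2, and 28 without Ceefourin 2 replicate 1. The 30 fell to 6 and 7, 17 and 5, and 2 and 9 in the first 3 of these pairs, and to 14 and 16 without Ceefourin 2 replicates 1 and 2. Across 530 genes called in either state, which are not independent replicates, 82.8% had the same sign, with Pearson's r of 0.58 and Spearman's rho of 0.68. Over all 17314 tested genes, 62.8% had the same sign, with Pearson's r of 0.30 and Spearman's rho of 0.34.

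**Figure D4:**
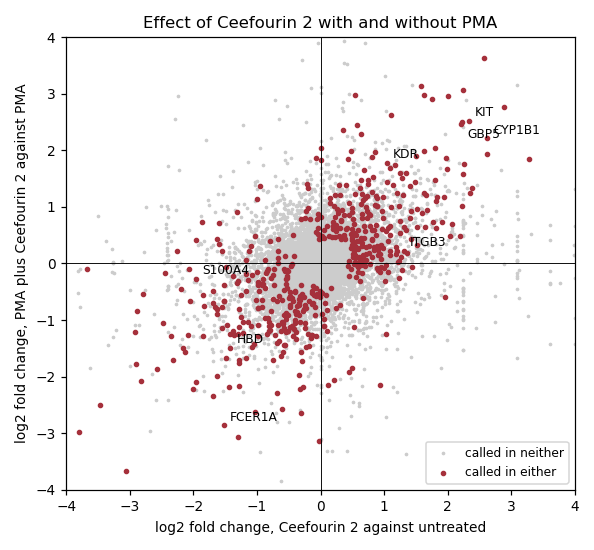
Log2 fold change of each tested gene with Ceefourin 2 alone (horizontal) and with Ceefourin 2 in PMA cells (vertical), with genes called in either comparison in red. Both axes run from -4 to 4, which leaves 79 of 17314 genes outside, and 45 genes were called higher and 30 lower in both.

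The interaction test asked whether the effect of Ceefourin 2 differed with PMA. In edgeR, 2 genes were called higher and 0 lower, with 1234 genes at an unadjusted p below 0.05, and DESeq2 called 77 higher and 125 lower while limma voom called 0 in either direction. APOL3, an apolipoprotein L gene on chromosome 22, was at 11.3 ± 0.97 CPM in PMA and 29.1 ± 3.8 CPM with the inhibitor added, and at 5.90 ± 0.80 CPM in untreated and 3.06 ± 0.062 CPM in Ceefourin 2 cells (interaction log2 fold change 2.31, SE 0.22, adjusted p = 0.047). S100A4 was at 131 ± 11 and 109 ± 10 CPM in the PMA groups without and with the inhibitor, and at 99.5 ± 2.9 and 25.6 ± 2.2 CPM without PMA (1.68, SE 0.15, adjusted p = 0.047). Neither stayed called without any of the 8 libraries. ABCC4 had an interaction of 0.01 (SE 0.14, adjusted p = 1), CYP1B1 of -0.41 (adjusted p = 0.55) and HBA2 of 1.12 (adjusted p = 0.14). ITGB3, called with Ceefourin 2 alone and not in PMA cells, had -1.09 (SE 0.13, adjusted p = 0.057), and FADS2 had the same adjusted p at -1.28. In this fit, a call in only one state therefore does not show a difference between the states for genes other than these 2. With the replicate number as a block, 114 genes were called higher and 133 lower in the interaction, among them ITGB3 and FADS2 (both adjusted p = 0.007) and HBA2 (0.024), so that number depends on whether the block is used.

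As lists, 26 of 26 cholesterol genes had a negative interaction, with a median of -0.60. DHCR7 was at 277 ± 27 and 427 ± 10 CPM without and with Ceefourin 2 in the absence of PMA, and at 174 ± 23 and 140 ± 13 CPM with PMA (interaction -0.93, adjusted p = 0.17, and 0.015 with the replicate block). Of the cholesterol genes 16 were called when adjusted over the list alone, as were 5 of 16 fatty acid and 10 of 21 chaperone genes, and 0 over all genes. DNAJB11 had an interaction of -0.59 (adjusted p = 0.18). It was called with the replicate number as a block, as were PLEK, ADCY6 and KDR below. Erythroid genes had a median interaction of 0.64, with 11 higher and 1 lower when adjusted over the list alone. The camera adjusted p of the cholesterol, fatty acid, chaperone and erythroid lists were 2.03e-15, 5.15e-08, 9.77e-10 and 3.79e-10, with adjusted p = 0.37, 0.37, 0.37 and 0.46 with an estimated correlation. Platelet and megakaryocyte proteins had a median of -0.41 (adjusted p = 0.00281, adjusted p = 0.68 with an estimated correlation), with PLEK at -0.99 (adjusted p = 0.17). Immediate early genes had a median of -0.34 (adjusted p = 0.00364, adjusted p = 0.85 with an estimated correlation), and lost the call without PMA replicate 2 (0.052), PMA plus Ceefourin 2 replicate 1 (0.24) or Ceefourin 2 replicate 2 (0.051). Cyclic AMP genes had a median of -0.19, with ADCY6, an adenylate cyclase, at -1.0 (list adjusted p = 0.0177, adjusted p = 0.37 with an estimated correlation). Their call was lost without untreated replicate 2 (0.16), PMA replicate 1 (0.055) or Ceefourin 2 replicate 1 (0.083). Endothelial genes, with KDR at 0.75, and stem and progenitor genes had medians of 0.46 and 0.20, both with adjusted p = 0.0167 and adjusted p = 0.62 with an estimated correlation. The endothelial call was lost without untreated replicate 2 (0.16), PMA plus Ceefourin 2 replicate 1 (0.14) or Ceefourin 2 replicate 2 (0.054), and the stem and progenitor call without untreated replicate 1 (0.14) or Ceefourin 2 replicate 2 (0.36). Both calls were also lost without PMA replicate 2, at an adjusted p that rounds to 0.05, and the endothelial call with the replicate block (0.055). With PMA replicate 1 and PMA plus Ceefourin 2 replicate 1 both left out, the endothelial, stem and progenitor, cyclic AMP and immediate early calls were lost (adjusted p = 0.12, 0.071, 0.071 and 0.12). Camera called 9 of 39 lists, 3 higher and 6 lower, and fry called 0, with 15 lists at a mixed adjusted p below 0.05.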

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

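The tests of scaling and of low counts, and the reading of single libraries against 0, were chosen after the result was seen, and the tests of single libraries against a bound were written down before their values were looked at. In the main fit the effect of Ceefourin 2 differed with PMA by the interaction test in 2 genes and 9 lists. The number of genes depended on the fit, with 0 called in limma voom and 114 higher and 133 lower with the replicate number as a block. The interaction log2 fold change was 2.31 for APOL3 and 1.68 for S100A4, and neither stayed called in any of the 8 fits without 1 library. Of 39 lists, 0 were called with an estimated correlation (lowest adjusted p = 0.37) and 0 with fry (lowest adjusted p = 0.078). Median interaction log2 fold changes were -0.41 for platelet and megakaryocyte proteins, 0.64 for erythroid genes, 0.46 for endothelial genes, 0.20 for stem and progenitor genes, -0.19 for cyclic AMP genes, -0.34 for immediate early genes, -0.60 for cholesterol genes, -0.44 for fatty acid genes and -0.46 for endoplasmic reticulum chaperones.

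Over 63 cholesterol, fatty acid and chaperone genes the median log2 fold change with Ceefourin 2 was 0.56 without PMA, where 14 were called higher, and -0.02 in PMA cells, where 0 were. With an estimated correlation between genes camera called none of the 3 lists in the interaction, and fry called none either (adjusted p = 0.078 for each). Whether the lists differ between the states therefore depends on the test. The estimated correlation in camera also changes the degrees of freedom, so the loss there cannot be put down to correlation between members alone. Changing between 4 scalings did not remove the difference, since the interaction median nearest to 0 was -0.54 (95% bootstrap interval over genes -0.60 to -0.46). These scalings held the median interaction of all genes between -0.05 and 0, so they could not test a larger scaling error. Leaving out any 1 library did not remove the difference, with the median nearest to 0 at -0.45 (-0.52 to -0.36), without PMA replicate 1. These bootstrap intervals treat the genes as independent and do not measure variation between libraries. A biological difference between PMA-treated and untreated cells remains a hypothesis, found and tested on the same data, and culture conditions that differ between the groups were not tested.

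Over 31 erythroid genes the median with Ceefourin 2 was -1.14 without PMA, where 14 were called lower, and -0.26 in PMA cells, where 3 were. The interaction of the list was not called with an estimated correlation (adjusted p = 0.46) or with fry (0.22), so whether the list differs between the states depends on the test. Changing between 4 scalings did not remove the difference, with a lowest interaction median of 0.49 (0.34 to 0.70). As above, these scalings differed too little to test a larger scaling error, and the bootstrap intervals do not measure variation between libraries. Low counts in PMA cells did not account for the difference, since the 23 members with a mean of at least 10 CPM in the PMA group had a median of 0.55 (0.39 to 0.78). Without untreated replicate 2 the median was lowest, at 0.47 (0.25 to 0.71), and camera called the list in each of the 8 fits without 1 library (highest adjusted p = 3.8e-06), so no single library was the whole cause. How much of the size rests on 1 library stays open, since that interval reached the bound of 0.25 set beforehand. The median of the erythroid list was already lower after PMA (-1.05), with 20 genes lower and 9 higher. With an estimated correlation camera did not call that fall (adjusted p = 0.55). A prior fall stays open as a biological explanation and was not tested.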

How the results depend on the processing

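Of 3217 combinations of a named gene and an alternative, 2792 kept the call or its absence, 393 lost the call, 32 gained one and 0 turned direction with a call. The count of turned directions tests little. Called genes had passed the test on the same libraries, and the largest rises and falls were named only where libraries did not overlap. For lists, 629 of 764 combinations kept the call, 134 lost it and 1 turned, the ATF4 list with Ceefourin 2 alone without Ceefourin 2 replicate 2 (adjusted p = 0.015). Without 1 library the adjusted p of that list ranged from 1.1e-18 to 0.5. Leaving out both PMA-treated libraries of high mitochondrial share, and removing mitochondrially encoded genes, were chosen after seeing the data. Fits on fewer libraries have fewer residual degrees of freedom and less power, and for other changes the cause was not tested. Libraries held 44430292 to 89950886 counts. Depth limits genes with few counts, and no fit on thinned counts was run, so depth and the number of libraries were not compared as limits on the calls.

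For PMA against untreated, limma on log2(TPM + 1) gave 3197 higher, and leaving out both high mitochondrial libraries gave 2884 lower. Without 1 library, higher calls ranged from 3903 to 5010 and lower calls from 3295 to 4501. For PMA plus Ceefourin 2 against PMA, the DESeq2 Wald test gave 443 higher and 330 lower, no filter 685 and 526, log2(TPM + 0.1) 69 higher, and leaving out both high mitochondrial libraries 0 and 1. Without 1 library, higher calls ranged from 12 to 169 and lower from 9 to 155. For Ceefourin 2 against untreated, the DESeq2 Wald test gave 488 higher and 312 lower, no filter 696 and 478, only the 2 groups compared 15 and 16, and leaving out both high mitochondrial libraries 23 and 18. Without 1 library, higher calls ranged from 14 to 103 and lower from 16 to 85. For the interaction, DESeq2 size factors gave 4 higher and 1 lower, the DESeq2 Wald test 77 and 125, limma voom 0 higher, log2(TPM + 1) 10 and 9, log2(TPM + 0.1) 5 and 3, no filter 171 and 243, at least 1 CPM in 2 libraries 0 higher, and leaving out both high mitochondrial libraries 0 higher. Without 1 library, higher calls ranged from 0 to 2 and lower from 0 to 1.

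With camera at an estimated correlation 0 lists were called in every comparison, and fry called 29, 6, 12 and 0 for PMA, PMA plus Ceefourin 2, Ceefourin 2 and the interaction. Without 1 library, called lists ranged from 15 to 17, 10 to 16, 9 to 14 and 8 to 12 in the same order, and without both high mitochondrial libraries 5 were called in the interaction. Leaving out 1 library gave 8 to 34 genes raised in both states, 2 to 17 lowered in both, and 11 to 112 opposed. Without both high mitochondrial libraries these were 0, 1 and 1.

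Replicate numbers are not documented as a shared day or passage, so the replicate block was kept as an alternative only. Deviations from the group means correlated between groups at the same number at 0.36 to 0.82 over 9454 genes, with 2 numbers only. Component 3 of log2 CPM, with 4.6% of variance, was positive in every replicate 1 and negative in every replicate 2. The main fit leaves such shared deviation in the residual spread, so its counts of calls are those of an unpaired fit. With the replicate block 12 results of named genes gained a call, which were ABCC4 with Ceefourin 2 in PMA cells (adjusted p = 0.031) and without PMA (0.038), ABCB1 (0.0063) and PRIM1 (0.036) in PMA cells, and in the interaction ITGB3, FADS2, KDR, DHCR7, ADCY6, DNAJB11, HBA2 and PLEK. With the block, PMA against untreated had 5667 higher and 5489 lower, PMA plus Ceefourin 2 against PMA 821 and 661, Ceefourin 2 against untreated 807 and 623, and the interaction 114 and 133. The block gave 289 genes raised and 210 lowered in both states and 528 opposed.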

Other observations

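EREG, an EGF receptor ligand, rose with Ceefourin 2 by 0.93 (SE 0.08, adjusted p = 0.004) in PMA cells and by 1.43 (SE 0.09, adjusted p = 0.00082) without PMA. NEDD9, an adhesion scaffold (0.70, adjusted p = 0.13), SLC7A5, an amino acid transporter (0.28, adjusted p = 0.72), CYP2S1 (-0.04, adjusted p = 0.99) and NQO1 (-0.07, adjusted p = 0.96) were not called in PMA cells, and none of them was called without PMA. These 5 genes were among 7, with ASB2, whose counts were too low to test, that were written down as further aryl hydrocarbon receptor targets before their values were looked at.

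The tests of scaling, and the reading of single libraries against 0, were chosen after the result was seen, and the other tests were written down first. The hypothesis was that Ceefourin 2 raises aryl hydrocarbon receptor targets in general, in both states. The 6 list members had medians of 1.45 without PMA and 1.21 with it. The lower median of the 6 further targets tested was 0.49, in PMA cells, and its 95% bootstrap interval of -0.05 to 1.92 spans the bound of 0.25, so the hypothesis may hold for some targets and was not settled for targets in general. A scaling error moves every gene alike, but the list median exceeded the median of all genes by at least 0.76 (0.39 to 1.91) under each of 4 scalings, so scaling was not the whole cause. This excess largely restates the list call and is no separate evidence for the effect. The bootstrap intervals here resample genes as if independent and do not measure variation between libraries. Over fits without 1 library the lowest median was 1.10 (0.31 to 2.47), and camera called the list in each of these fits in both states (highest adjusted p = 1e-05), so no single library was the whole cause either. With 6 genes, that interval and the interval of the lowest median over scalings, 0.77 (0.41 to 1.93), reach below a bound of 0.5, so a part of the size may still rest on either. With an estimated correlation the list was not called in either state (adjusted p = 0.14 without PMA and 0.18 with it). Whether any such effect comes from ABCC4 inhibition or from the compound itself was not tested, since the design holds 1 inhibitor and no other means of lowering ABCC4 activity.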
